A study of Mus musculus with 6 samples.

How the data were processed

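Expression was measured in E14 mouse embryonic stem cells on feeder fibroblasts with an Affymetrix whole-transcript gene array for mouse, in 6 samples: 2 untreated, 2 exposed to 0.5 mM VPA and 2 exposed to 0.2 mM NaBu for 16 h. The values deposited by the authors are log2 expression per probeset, 1 column per array, made with RMA in Affymetrix Expression Console 1.1 per the submitters' processing notes. The settings of RMA and the library files are not given in the sources used here. The labels number the replicates 1 and 2 but do not say whether they are separate cultures, so each p-value measures the spread between samples only. The number of arrays limits the precision, and no genome build is named for the values, so no coordinates are printed.

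The table held 35556 probesets, of which 23410 were in the probe annotation and 12146 were not listed there. A single gene symbol stood beside 21789 probesets and several symbols beside 1621, and probesets with several symbols were not used for named genes. Symbols were compared with the RefSeq annotation of GRCm38.p6 for names only. For the 999 genes with more than 1 probeset, the probeset with the highest mean over the 6 arrays stood for the gene, which left 19938 genes. The 13767 probesets not listed or with several symbols were tested separately, and limma called 0 of them in each of the 3 comparisons, with 562, 690 and 630 at an unadjusted p under 0.05 for VPA, NaBu and VPA against NaBu.

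Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with 1 mean per group over the 6 arrays, which leaves 3 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes at a threshold of 0.05. All intervals of single genes are 95% intervals from this model. The smallest p of a two-sided exact permutation test of 2 against 2 arrays is 0.333, so none was used. The tests, the gene lists and the rule for named genes were fixed before the data were examined. Whether the replicate numbers pair the samples was read from the deposited values and not from the labels: same-numbered arrays deviated from their group means together. A model with the replicate number as a block, which leaves 2 residual degrees of freedom, is therefore given beside the unblocked one.

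Gene lists were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 24 lists. The lists were naive and core pluripotency, primed epiblast, neural progenitor, neuronal and REST-target, primitive streak and mesoderm, endoderm, trophectoderm, germline, 2-cell-like state, known inhibitor-induced, known inhibitor-repressed, histone deacetylases and acetyltransferases, histones, cell cycle, p53 targets, feeder fibroblast, fatty acid oxidation, cholesterol synthesis, glycolysis and hypoxia, endoplasmic reticulum and amino acid stress, oxidative stress, imprinted, Hox and Wnt target genes. With a correlation estimated for each list, camera called 0 lists in the 3 comparisons, with 1, 0 and 1 at an unadjusted p under 0.05, and the self-contained test fry also called 0, so that all 16 list calls were lost under both. With the replicate block an estimated correlation again called 0, fry kept 3 of the 9 calls for VPA and 3 of the 5 between the compounds, and limma on list means kept 2 for VPA. Members of a list were also counted at an adjusted p under 0.05 adjusted over the list alone. An error between arrays for a list came from limma on the 24 list means per array.

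Named genes followed a fixed rule. It took genes at an adjusted p under 0.05 or, where fewer than 6 passed in a direction, those with the largest moderated statistic up to 6 (5 for VPA against NaBu), the 3 members of each list with the largest statistic for each compound, and 13 genes named in any case. The first part left out symbols that start with LOC, Olfr, Vmn, Mir, Snor or n-R5s, with Gm, AI, AU, BC or BB before digits, or that end in Rik. This pattern keeps other clone names and small RNAs, such as AW209491 and Rny3. H1f0, Cdkn1a and Gapdh, which the rule also names, are not analysed here because no probeset carried their symbol alone. For the same reason the 2-cell-like list holds 21 genes from 38 written symbols and lacks Zscan4a to Zscan4f, Dux and Tcstv1. The histone list holds 28 genes from 60 written symbols and lacks Hist1h3a, Hist1h3b, Hist1h3c and others. Genes named outside the rule are said to have been chosen after their values were seen.

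The procedure was tested on simulated data for VPA against control over 19938 genes. Of 100 genes with an added log2 change of 1, 44 were recovered without the block and 99 with it, and of 100 with a log2 change of 2, 96 and 99. There were 0 false calls without the block and 25 with it. A shift of -0.30 added to the pluripotency list was recovered by camera with its preset correlation. With no gene changed 0 genes were called without the block, and this run was not made with the block. Errors were drawn independently for each gene, while the estimated correlation of the real pluripotency list was 0.23. The simulation therefore does not test list calls among correlated genes. Alternatives were the replicate block, fits to 2 groups, filters on dim genes, median centring, quantile normalization, other handling of probesets, a trend with robust eBayes, array weights, a minimum change of 1.1-fold, other set tests and leaving out each array. Except where a block is named, arrays were left out in fits without it. A group with 1 array left then differs from the others in replicate number too, so part of that difference enters its comparisons. Shared responses were compared with 100 simulations of unchanged groups, drawn with the spread of each gene in the blocked model.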

Results

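Mouse E14 embryonic stem cells, which grow as an undifferentiated line in the presence of the cytokine LIF on a layer of growth-arrested fibroblasts, were left untreated or exposed for 16 h to a low level of a histone deacetylase inhibitor. The compounds were valproic acid (VPA, 0.5 mM) and sodium butyrate (NaBu, 0.2 mM), both short-chain fatty acids, of which VPA has a branched chain and butyrate a straight one. RNA from 2 samples per condition was hybridised to 6 one-colour arrays, and expression of 19938 genes was compared as log2 intensity. The median probeset had a log2 value between 5.01 and 5.09 on every array.

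The arrays differed most by replicate number, not by treatment. The first principal component held 53.6% of the variance and put replicate 1 of each condition on one side and replicate 2 on the other, and the second held 22.2%. After the mean of each condition was taken away, the deviations of same-numbered arrays correlated across genes with r = 0.558 for control and VPA, 0.693 for control and NaBu, and 0.567 for VPA and NaBu. The numbers were therefore also used to pair the samples into replicate set 1 and replicate set 2, and differences within each set stand beside the pooled values.

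**Figure D1:**
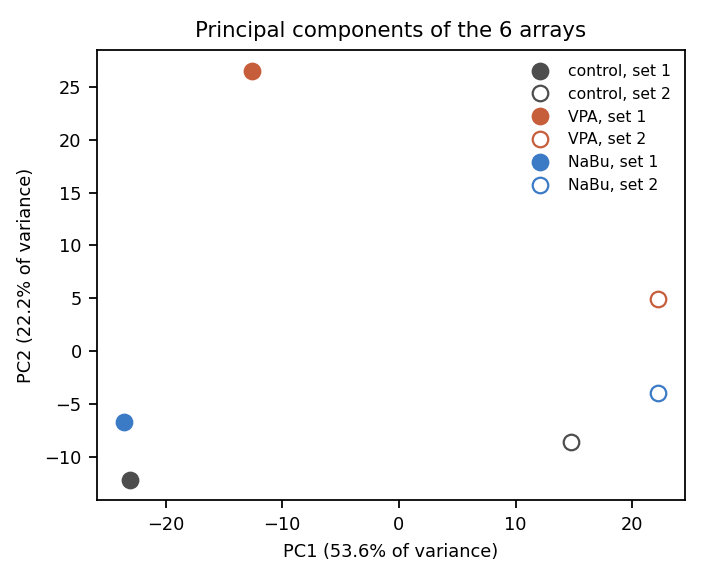
Each point is 1 of the 6 arrays, placed by its scores on the first and second principal components of the log2 values of 19938 genes, in color by treatment and filled for replicate set 1 or open for replicate set 2. The first component, with 53.6% of the variance, separates the sets, and the second, with 22.2%, places VPA replicate 1 apart from the other arrays.

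The comparison of VPA with untreated cells asked how a low level of the inhibitor alters expression in stem cells kept under conditions for self-renewal. Genes of the pluripotency network fell as a group (adjusted p = 0.512 with an estimated correlation). The 32 measured members had a mean log2 difference of -0.36, and 28 lay below 0, 25 of them in both replicate sets. Pou5f1, which encodes the core pluripotency factor Oct4, had a log2 difference of -0.64 (95% interval -0.97 to -0.31), with a mean of 11.77 ± 0.19 (SD, n = 2) in untreated cells. Prdm14, a repressor of differentiation genes, stood at -1.25 (95% interval -1.92 to -0.57), and Utf1, a chromatin-bound marker of undifferentiated cells, at -0.59. Nanog stood at -0.46, Zfp42 at -0.31, Esrrb at -0.30 and Klf4 at -0.19, whereas Sox2, the partner of Oct4, stood at -0.02 (95% interval -0.48 to 0.43). The list passed the camera test at an adjusted p of 2.0e-10 and was lost at adjusted p = 0.512 with an estimated correlation. Its mean was -0.46 in replicate set 1 and -0.27 in replicate set 2, and -0.24 when control replicate 1 was left out. With an error taken between arrays, the mean of the list had a 95% interval of -0.72 to -0.00 (adjusted p 0.706 over the 24 lists), and of -0.58 to -0.15 with the replicate block (adjusted p 0.0873). It did not pass in either, nor with the block and fry (adjusted p 0.149). Feeder fibroblast markers moved apart between the sets, with a mean of -0.13 in set 1 and 0.21 in set 2.

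Genes of S phase and mitosis fell by a smaller and more even amount with VPA (adjusted p = 0.512 with an estimated correlation). Of the 43 measured cell cycle genes, 41 lay below 0, 39 in both sets, and the mean was -0.21, with -0.20 in set 1 and -0.22 in set 2. Nusap1, a spindle protein, stood at -0.53 (95% interval -0.83 to -0.23), the mitotic kinase Plk1 at -0.42 and the kinesin Kif20a at -0.33. The list passed at an adjusted p of 3.0e-10 (adjusted p = 0.512 with an estimated correlation), and its mean was -0.14 without VPA replicate 2. Genes reported in many cell types as repressed by histone deacetylase inhibitors fell too (adjusted p = 0.573 with an estimated correlation), with 14 of 15 members below 0 and a mean of -0.23. Among them Ccnd1, which encodes cyclin D1, stood at -0.84, Birc5 at -0.35 and the checkpoint kinase Chek1 at -0.29, and 5 members are also in the cell cycle list. This list had an adjusted p of 0.000141 (adjusted p = 0.573 with an estimated correlation) and a mean of -0.12 without control replicate 1. The feeder markers stood at -0.13 in set 1 and 0.21 in set 2, each a difference between single arrays. Whether feeder RNA contributed to the fall of the cell cycle genes was not tested. With an error taken between arrays neither list passed, at an adjusted p of 0.706 and intervals of -0.54 to 0.08 for the repressed and -0.47 to 0.05 for the cell cycle list. With the replicate block as well, both had an adjusted p of 0.0358. With the block and fry both had an adjusted p of 0.0233, against 0.377 in camera with the block and an estimated correlation.

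The list of histone deacetylases, acetyltransferases and subunits of their complexes also fell as a group with VPA (adjusted p = 0.512 with an estimated correlation). Of its 44 measured members, 30 lay below 0 and the mean was -0.10. The acetyltransferase Kat2b stood at -0.98 (95% interval -1.46 to -0.51), the corepressor Rcor2 at -0.62 and the Sin3 complex subunit Sap30 at -0.44. The deacetylases Hdac1 and Hdac2 stood at 0.11 and -0.09. The list fell at an adjusted p of 0.00202 (adjusted p = 0.512 with an estimated correlation). Histone genes, of which 28 were measured from 60 written symbols, fell slightly, with 22 of 28 below 0 and a mean of -0.08. Their adjusted p was 0.0114 (adjusted p = 0.724 with an estimated correlation). H2ac4 stood at -0.42, while H2ac1, a testis-enriched variant, stood at 0.92 and the linker histone H1f2 at 0.44. The histone list lost its call without control replicate 2 (mean -0.02), without VPA replicate 1 (-0.03) and among genes at or above the median level (-0.04), and its mean was -0.14 without control replicate 1 and -0.12 without VPA replicate 2. Markers of the primed epiblast, the state that follows naive pluripotency in the embryo, fell at an adjusted p of 0.0475 (adjusted p = 0.512 with an estimated correlation), with 16 of 22 below 0 and a mean of -0.19. Otx2 stood at -0.61 and Etv5 at -0.22, but the tight junction gene Cldn6 stood at 0.85. The epiblast call was lost when any of control replicate 1 (-0.18), control replicate 2 (-0.19) or VPA replicate 1 (-0.08) was left out and with median centring, quantile normalization or either filter on dim genes, and the mean was -0.29 without VPA replicate 2. With the block and an error between arrays the adjusted p was 0.0956 for the deacetylase, 0.259 for the histone and 0.217 for the epiblast list. With the block and fry the values were 0.0233, 0.341 and 0.317 in that order. The deacetylase list had an adjusted p of 0.377 in camera with the block and an estimated correlation.

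Genes of neurons rose as a group with VPA (adjusted p = 0.724 with an estimated correlation). Many of them are silenced outside the nervous system by the repressor REST with its deacetylase partners. Of the 47 measured neuronal and REST-target genes, 35 lay above 0, 27 in both sets, and the mean was 0.17, with 0.23 in set 1 and 0.12 in set 2. Map2, a dendritic microtubule protein, stood at 0.69 (95% interval 0.05 to 1.32), the adhesion molecule L1cam at 0.43 and the sodium channel Scn2a at 0.40. The list passed at an adjusted p of 0.00124 (adjusted p = 0.724 with an estimated correlation), and its mean was 0.11 without control replicate 1. Germ cell genes rose at an adjusted p of 0.00768 (adjusted p = 0.724 with an estimated correlation), with 30 of 38 above 0 and a mean of 0.21. The testis bromodomain gene Brdt stood at 0.86, Tex11 at 0.75 and Mov10l1 at 0.56. The germline mean was 0.41 in set 1 and 0.01 in set 2, and the call was lost without VPA replicate 1, where the mean was -0.04, against 0.45 without VPA replicate 2. Trophectoderm markers rose at an adjusted p of 0.0475 (adjusted p = 0.724 with an estimated correlation), with 17 of 24 above 0 and a mean of 0.20, split into 0.34 in set 1 and 0.06 in set 2. Tfap2c, a regulator of the trophoblast lineage, stood at 0.95, the receptor Fgfr2 at 0.39 and the imprinted growth restrictor Phlda2 at -0.58. The trophectoderm call was lost without control replicate 1 (0.07), without VPA replicate 1 (0.19), after quantile normalization (0.18) and among genes at or above the median level (0.31), and the mean was 0.33 without control replicate 2. In set 1, where the germline and trophectoderm lists were highest, the feeder markers had a mean of -0.13, a difference between single arrays. A share of feeder RNA was not tested as a cause for these lists. With an error between arrays and the block the adjusted p was 0.191 for the neuronal, 0.267 for the germline and 0.259 for the trophectoderm list.

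The other 15 lists did not pass in VPA against control. Genes reported as induced by histone deacetylase inhibitors had a mean of 0.10, with 19 of 29 above 0, Clu at 0.97 and the metallothionein Mt1 at 0.51. The p53 targets had a mean of 0.10 (Pmaip1 0.55, Rrm2b 0.46), imprinted genes 0.12 (Nnat 1.16, Igf2r 0.71), 2-cell-like genes 0.11 (Usp17ld 0.99), oxidative stress genes 0.08 (Gclc 0.41), fatty acid oxidation genes 0.08 (Acadl 0.42) and Hox genes 0.08 (Hoxd8 0.27). Lineage lists stayed closer to 0, with endoderm at 0.06 (Plat 0.77, Gata6 -0.34), neural progenitors at 0.04 (Nes 0.41, Dll1 -0.34) and mesoderm at 0.03 (Kdr 0.53, Gsc -0.30). The means were 0.02 for glycolysis and hypoxia (Tpi1 -0.32), 0.00 for cholesterol synthesis (Fasn -0.46), -0.03 for Wnt targets (Axin2 -0.22) and -0.04 for stress of the endoplasmic reticulum and amino acid supply (Slc7a3 -1.03). The test pointed down for glycolysis and cholesterol genes although their means lay above 0, and the endoderm median was -0.00. The feeder list had a mean of 0.04, with Col1a1 at 0.18, and the cytoskeletal gene Actb stood at 0.04. Leaving out VPA replicate 1 or VPA replicate 2 moved 10 of these 15 means across 0. The 2 values were -0.17 and 0.39 for 2-cell-like genes, 0.39 and -0.31 for feeder markers, 0.38 and -0.34 for glycolysis and hypoxia, and 0.17 and -0.25 for stress of the endoplasmic reticulum. They were -0.02 and 0.17 for fatty acid oxidation, -0.01 and 0.18 for oxidative stress, 0.13 and -0.02 for endoderm, 0.08 and -0.08 for cholesterol, -0.01 and 0.07 for mesoderm and -0.07 and 0.00 for Wnt targets, and the inhibitor-induced mean was 0.01 without control replicate 1. Each of these fits had no block and left 1 array in a group, so part of the difference between the replicate sets entered the mean. Within sets 1 and 2 the means were 0.003 and 0.039 for glycolysis and hypoxia. They were -0.07 and -0.01 for stress of the endoplasmic reticulum. With the block, leaving out VPA replicate 1 gave 0.002 and -0.02 for these 2 lists. It gave 0.16 for feeder markers and 0.11 for 2-cell-like genes.

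No single gene passed an adjusted p of 0.05 for VPA. limma called 0 of 19938 genes, with a smallest adjusted p of 0.964, and 981 genes had an unadjusted p under 0.05 (547 higher and 434 lower). Uniform p-values would give 997. This model leaves the replicate-set difference in its error, so a count near or below that value does not show a lack of effect. With the replicate block limma again called 0 genes, with a smallest adjusted p of 0.201 and 2636 unadjusted, above the 997. Genes are not independent, so the size of this count was not tested. In no list did a member pass adjusted over the list alone, whereas with the block 16 of the 32 pluripotency genes passed adjusted over the list alone, all lower. So did 5 of 21 2-cell-like genes, 4 of 29 inhibitor-induced genes and 3 or fewer in each other list. The blocked model made 25 false calls in simulated data of 19938 genes, adjusted over all genes. That count gives no error rate for calls adjusted over 1 list, and the blocked model was not run with no gene changed. The largest moderated statistics belonged to the integrin Itga8 (1.00), the calpain Capn6 (0.86), the vitamin D receptor Vdr (0.62), Amot (0.63), the collagen Col11a1 (0.71) and C1ql4 (0.60) among higher genes. Among lower genes they belonged to Cyp2b23 (-1.39), AW209491 (-0.69), Akip1 (-0.58), the actin nucleator Cobl (-0.78), Kat2b (-0.98) and Rassf7 (-0.58). Untreated means of these higher genes ran from 4.61 (Amot) to 5.38 (Col11a1), below the medians of the 19938 genes on the untreated arrays, 5.732 and 5.765. Those of these lower genes lay above the medians.

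**Figure D2:**
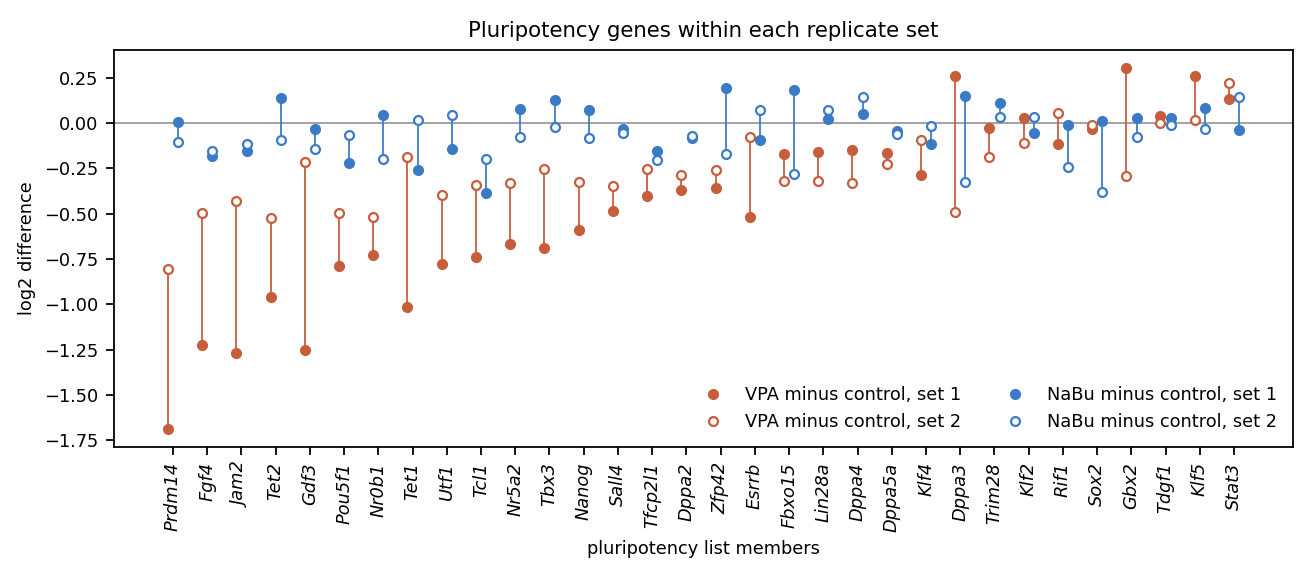
Points are log2 differences from the untreated array of the same replicate set for the 32 pluripotency genes, ordered by their mean difference with VPA, in red for VPA and blue for NaBu, filled for set 1 and open for set 2, and each line joins the 2 sets. With VPA 25 genes lie below 0 in both sets, against 11 with NaBu.

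The comparison of NaBu with untreated cells asked the same question of the other inhibitor. Germ cell genes rose and histone genes fell, and these were the lists that passed, both with adjusted p = 0.998 with an estimated correlation. Of 38 germline genes, 32 lay above 0, 24 in both sets, and the mean was 0.16, with 0.23 in set 1 and 0.10 in set 2. Mov10l1 and Tex11 both stood at 0.40, and Stk31 at 0.37 (95% interval 0.07 to 0.67). The list had an adjusted p of 0.0206 (adjusted p = 0.998 with an estimated correlation), and the call was lost without control replicate 1 (0.21) or NaBu replicate 1 (0.06), with 0.27 without NaBu replicate 2. Of the 28 measured histone genes, 21 lay below 0, 15 in both sets, and the mean was -0.08. H4c8 stood at -0.40 and H2ac15 at -0.27, while H3c7 stood at 0.42. The histone list had an adjusted p of 0.00823 (adjusted p = 0.998 with an estimated correlation), lost its call without control replicate 2 (-0.02) or NaBu replicate 1 (-0.08), and had a mean of -0.14 without control replicate 1. In the blocked model with an error between arrays the adjusted p was 0.754 for the germline and 0.689 for the histone list. Feeder markers stood higher with NaBu by a mean of 0.12, with 0.01 in set 1 and 0.23 in set 2, and Col1a1 at 0.41 (95% interval -0.94 to 1.76). Their mean was -0.16 without NaBu replicate 2 and -0.06 without control replicate 1, against 0.30 without control replicate 2 and 0.41 without NaBu replicate 1.

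With NaBu the pluripotency list did not pass. Its mean was -0.05 (adjusted p 0.309, 95% interval -0.41 to 0.31 with an error between arrays), with Pou5f1 at -0.14, Tcl1 at -0.29, Sox2 at -0.18, Tfcp2l1 at -0.18, Klf4 at -0.07, Nanog at -0.00, Esrrb at -0.01 and Zfp42 at 0.01. The list mean ranged from -0.21 without NaBu replicate 1 to 0.10 without NaBu replicate 2, and the list passed, lower, without NaBu replicate 1 or control replicate 2 (-0.18). These fits had no block, so part of the difference between the replicate sets enters them, and this list was lower in set 2 by a mean of -0.21. Within sets 1 and 2 the NaBu means were -0.02 and -0.08. The neuronal list had a mean of 0.02 (Elavl4 0.26, Stmn3 -0.59), the list of inhibitor-induced genes 0.02 (Tubb3 -0.30), that of inhibitor-repressed genes -0.04 (Birc5 -0.29), and the deacetylase and acetyltransferase list a mean of -0.00 (Kat2b -0.31, Sap30 -0.23). The sign of each of these list means changed with the NaBu replicate that was left out, in fits without the block. Within sets 1 and 2 the means were -0.03 and 0.08 for the neuronal and -0.01 and 0.04 for the inhibitor-induced list. They were -0.05 and -0.02 for the inhibitor-repressed and -0.011 and 0.001 for the deacetylase list. Hdac1 stood at 0.05, Hdac2 at 0.02 and Actb at -0.01. The test pointed down for the inhibitor-induced list although its mean and median lay above 0, and for the deacetylase list although its median did. The cell cycle list had a mean of -0.05 and an adjusted p of 0.125. With the replicate block that list passed at an adjusted p of 0.0212, the feeder list, which was higher, at 0.00126, and the 2-cell-like list, with a mean of 0.15, at 0.0496, and each of the 3 had adjusted p = 0.816 with an estimated correlation in the blocked model. With an error between arrays in that model the adjusted p was 0.689 for the cell cycle, 0.754 for the feeder and 0.689 for the 2-cell-like list. The 2-cell-like mean was 0.28 in set 1 and 0.02 in set 2, and without the block it ranged from -0.20 without NaBu replicate 1 to 0.49 without NaBu replicate 2. Without the block, the cell cycle mean was 0.01 without control replicate 1 and 0.02 without NaBu replicate 2, against -0.12 without NaBu replicate 1. Within sets 1 and 2 it was -0.04 and -0.07. Among the 2-cell-like genes Usp17ld stood at 0.99, with 1.89 in set 1 and 0.09 in set 2, and Zfp352 at 0.57.

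For single genes limma called 0 of 19938 with NaBu, with a smallest adjusted p of 1.00 and 311 genes at an unadjusted p under 0.05. With the replicate block it called 0, with 916 unadjusted and a smallest adjusted p of 0.994. The largest moderated statistics belonged to Plekhd1 (0.55), Ppp1r27 (0.48), Lyrm9 (0.59), the platelet chemokine Ppbp (0.89), Lrit3 (0.46) and the potassium channel Kcnj14 (0.74) among higher genes. Among lower genes they belonged to the small cytoplasmic RNA Rny3 (-0.76), Prp2 (-0.62), Btnl5-ps (-0.84), Ampd1 (-0.58), Gpr62 (-0.78) and Mug1 (-0.54). Most of these genes had low levels. Only Rny3 (11.42) and Prp2 (6.79) had untreated means above the medians of the 19938 genes on the untreated arrays, 5.732 and 5.765. The means were 3.46 for Ppp1r27, 3.52 for Lrit3, 3.53 for Mug1 and 3.82 for Plekhd1.

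**Figure D3:**
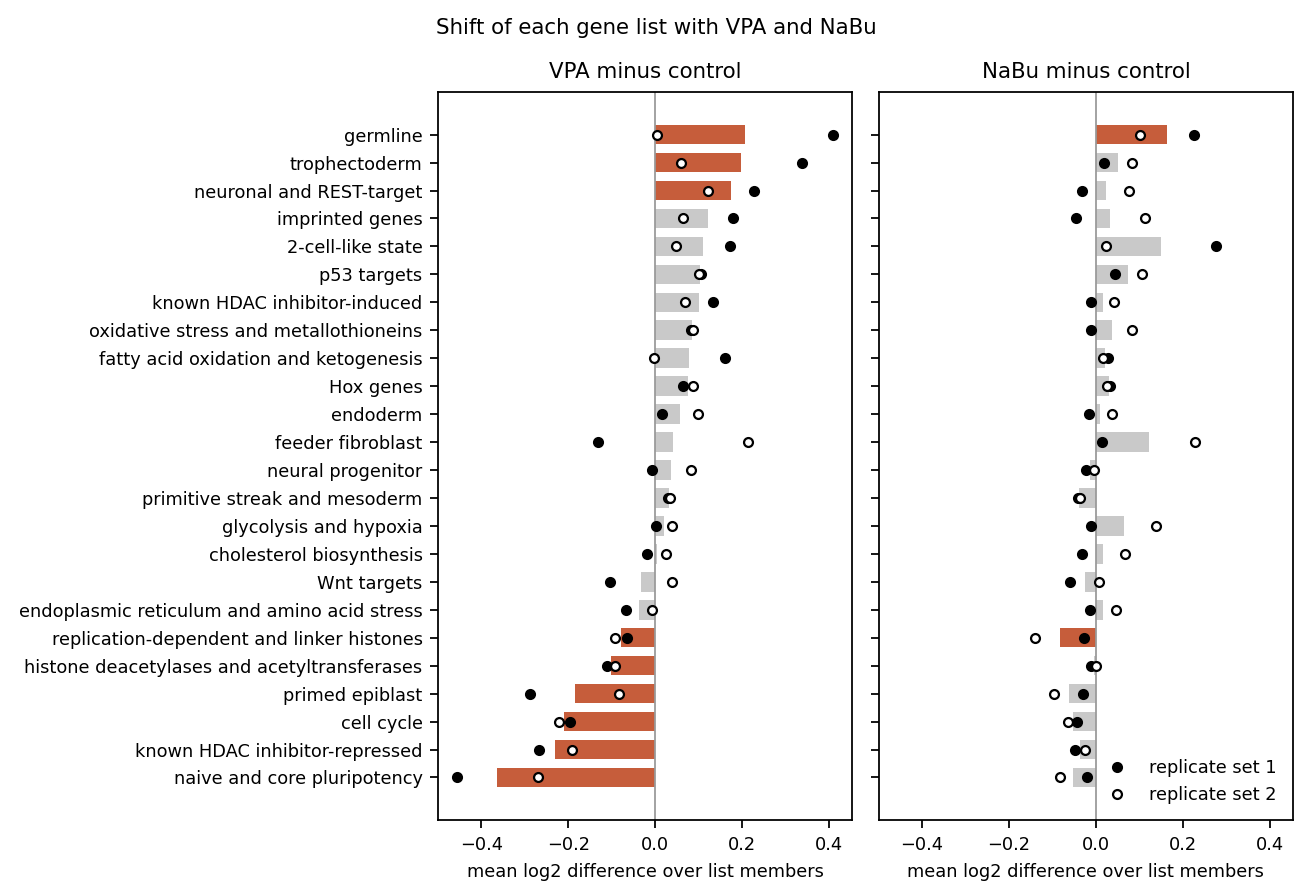
Bars give the mean log2 difference from untreated cells over the members of each of 24 gene lists, for VPA on the left and NaBu on the right, in orange for lists that passed camera with its preset correlation and grey for the others, and points give the mean in replicate set 1 (filled) and set 2 (open). The pluripotency list has the lowest bar with VPA, at -0.36, and stands at -0.05 with NaBu.

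The direct comparison of VPA with NaBu set the 2 conditions side by side as run, at doses that differ. The pluripotency genes were lower with VPA than with NaBu by a mean of -0.31, with 26 of 32 below 0 and -0.43 and -0.19 in the sets (adjusted p 6.35e-08, and adjusted p = 0.637 with an estimated correlation). Pou5f1 differed by -0.50 (95% interval -0.83 to -0.17). The cell cycle list was lower by -0.16, with 41 of 43 below 0 (adjusted p 1.18e-06, and adjusted p = 0.637 with an estimated correlation). The inhibitor-repressed list was lower by -0.19 (adjusted p 0.00168) and the deacetylase and acetyltransferase list by -0.10 (adjusted p 0.00353), and each had adjusted p = 0.637 with an estimated correlation. The neuronal list was higher with VPA by 0.15, with 34 of 47 above 0 (adjusted p 0.00168, and adjusted p = 0.637 with an estimated correlation). With an error taken between arrays none of these 5 lists passed, with a lowest adjusted p of 0.955, or of 0.0626 with the block. With the block and fry the cell cycle, inhibitor-repressed and deacetylase lists each had an adjusted p of 0.0265. The pluripotency (0.240) and neuronal (0.533) lists did not pass that test. With the block and an estimated correlation camera called none of them. Without NaBu replicate 1 none passed, with means of -0.15 for pluripotency, -0.08 for the cell cycle, -0.10 for inhibitor-repressed genes, -0.07 for the deacetylase list and 0.03 for the neuronal list. That fit had no block and set both VPA arrays against NaBu replicate 2 alone, so part of the set difference enters these means. Within sets 1 and 2 the cell cycle means were -0.15 and -0.16, with 38 of 43 genes below 0 in both. They were -0.22 and -0.17 for inhibitor-repressed genes, -0.10 and -0.09 for the deacetylase list and 0.26 and 0.05 for the neuronal list. Without VPA replicate 2 the neuronal (0.14) and inhibitor-repressed (-0.12) lists did not pass and the cell cycle mean was -0.08, and quantile normalization ended the call of the deacetylase list (-0.07). Without NaBu replicate 2 the means were -0.47 for pluripotency, 0.27 for the neuronal list and -0.29 for inhibitor-repressed genes.

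Germline and histone genes did not differ detectably between the compounds. The germline mean was higher with VPA by 0.04, with a 95% interval of -0.40 to 0.49 between arrays, and the histone mean by 0.01, with an interval of -0.21 to 0.23, although its test pointed down. The germline difference was 0.18 in set 1 and -0.10 in set 2, and its sign changed with the VPA replicate that was left out. The feeder list differed by -0.08 (interval -0.83 to 0.67). The germline and feeder intervals include a difference as large as the -0.31 of the pluripotency list. limma called 0 of 19938 genes between VPA and NaBu, with a smallest adjusted p of 0.998 and 724 unadjusted, and 0 with the replicate block, with 2150 unadjusted and a smallest adjusted p of 0.142. The largest moderated statistics belonged to C1ql4 (0.81, 95% interval 0.54 to 1.09), H2al2a (0.69), Itga8 (0.85), Cntnap1 (0.62) and Aqp11 (0.60) among genes higher with VPA. Sema5b (-0.56), Tia1 (-0.55), AW209491 (-0.57), Elp6 (-0.54) and the bromodomain gene Baz2b (-0.67) led the genes lower with VPA. The named genes higher with VPA had NaBu means from 3.25 (Cntnap1) to 5.58 (Aqp11), below the medians of the 19938 genes on the NaBu arrays, 5.712 and 5.787.

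Whether the compounds shifted the same genes was asked across all genes, which are not independent replicates. The log2 differences of VPA and NaBu from the shared untreated samples correlated with r = 0.469 and had a covariance of 0.0140. In 100 simulations of unchanged groups with shared controls, r was 0.500 on average (0.471 to 0.524) and the covariance 0.0109 (0.0101 to 0.0116), so the observed covariance exceeded the simulated mean by 0.00314. These simulations used the spread left after the replicate sets were taken out. With its moderated form the simulated covariance was 0.00827, and with the spread of the unblocked model, which ignores the pairing, 0.0273, above the observed value, and the observed r lay below the lowest simulated one. Neither the sign nor the size of an excess is therefore settled. The correlation was 0.0965 without NaBu replicate 2 and 0.760 without control replicate 2. When each compound was set against a different control, so that no array was shared, r was -0.281 and -0.0643. When each was set against the control of its own replicate set, r was 0.170 for VPA of set 1 with NaBu of set 2, and 0.0839 for VPA of set 2 with NaBu of set 1. Between its own sets VPA had r = 0.345 and NaBu r = 0.0908.

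Counted without a test, 273 genes differed by at least 1.5-fold with VPA with both treated arrays beyond both untreated ones, 156 higher and 117 lower. With NaBu there were 21, 12 higher and 9 lower. Whatever the size, this order held for 34.7% of genes with VPA and 23.9% with NaBu, where 33.3% would apply only to exchangeable arrays, which same-numbered arrays are not. Splitting the same 4 arrays by replicate set gave 739 genes (44.2% in order) for VPA and 1054 (54.0%) for NaBu. The crossed split, which parts the pairs as the real one does, gave 23 genes (20.8%) for VPA and 15 (21.9%) for NaBu, and 1 such split per compound allows no test. The germline mitochondrial carrier Slc25a31 (0.82 with VPA and 0.66 with NaBu), Abca8b (0.64 and 0.61) and AU015228 (1.44 and 0.73) were among the higher genes with both compounds. Stmn3 (-0.66 and -0.59) and n-R5s136 (-1.05 and -1.23) were among the lower genes with both, and the names of Slc25a31, AU015228, Abca8b and n-R5s136 were chosen after their values were seen. The overlaps were 3 higher and 2 lower genes, against 0.0939 and 0.0528 for lists drawn independently, which ignores the shared controls. In simulated unchanged groups with the replicate sets and shared controls they averaged 9.90 and 8.92 with each gene's own spread, which gave 92.5 genes for NaBu where 21 were seen. With the moderated spread they averaged 0.30 and 0.36, from 5.77 genes for NaBu. For VPA these 2 simulations gave 92.6 and 6.02 genes where 273 were seen, so neither matches the observed lists in size. The observed overlaps lie between the simulated ones, and an excess was neither shown nor excluded.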

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

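Alternatives that combine the block with another choice, the correlations within a replicate set, limma on list means, other spreads in the simulations and those for the difference between replicate sets were chosen after seeing the data. For single genes limma called 0 in all 3 comparisons under each single change of the processing, while the unadjusted count ranged from 336 to 2636 for VPA, 42 to 916 for NaBu and 278 to 2150 for VPA against NaBu. The exception was the block with the filter at the median level and robust eBayes with a trend, which called 43 genes for VPA (14 higher and 29 lower), 1 for NaBu and 0 between the compounds. Without both the trend and the robust form it called 0, and the 2 options were not separated. Under this setting Pou5f1 had an adjusted p of 0.0467 (0.0467 to 1.00 over all settings) and Rny3, the gene called for NaBu, one of 0.0265 (0.0265 to 1.00). Leaving out 1 of the 2 arrays of a group assumes that the other varies like the remaining groups.

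The number of lists called fell to 0 in each comparison with an estimated correlation, with fry, with the block and an estimated correlation, and with limma on list means. With the block and fry it was 3 for VPA, 1 for NaBu and 4 between the compounds, where the mesoderm list, called in the last 2, had not been called before, and with the block and limma on list means 2, 0 and 0. The block alone called 9, 5 and 5. When arrays were left out in turn, the count ranged from 7 to 16 for VPA, 2 to 7 for NaBu and 2 to 11 between the compounds. Over all settings the adjusted p of the 9 lists called for VPA reached up to 0.968, of the 2 for NaBu 0.998 and of the 5 between the compounds 0.955. The pluripotency, cell cycle, neuronal, inhibitor-repressed and deacetylase lists stayed called for VPA under each filter, normalization and left-out array.

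Lists that were not called became called against the direction of their test only where an array was left out. The means then ranged from -0.34 to 0.38 for glycolysis and hypoxia genes and from -0.31 to 0.39 for feeder markers with VPA. With NaBu they ranged from -0.35 (without NaBu replicate 2) to 0.48, with -0.28 without control replicate 1, for glycolysis and hypoxia genes, and from -0.10 to 0.14 for neuronal genes. Between the compounds they ranged from -0.20 to 0.29 for germline genes and from -0.43 to 0.27 for feeder markers. A further 84 of 1365 list values and 36 of 3177 values of named genes had the opposite sign without a call.

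The shared response reversed to r = -0.281 and -0.0643 with a different control for each compound, since this puts the difference between replicate sets into the 2 comparisons with opposite signs. With each compound against its own set's control r was 0.170 and 0.0839, and it ranged from 0.0965 to 0.760 over left-out arrays. The untested count moved from 273 to 18 at 2-fold and 2474 at 1.2-fold for VPA, and from 21 to 1 and 889 for NaBu, and to 8 for NaBu among genes at or above the median, where fewer genes are counted. List means with an array left out came from fits without the block and take in part of the difference between the replicate sets. For all other changes given here the cause was not tested.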

Other observations

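The tests in this part were chosen after the result was seen, except camera for VPA against control without VPA replicate 1, which was planned. The genes named for the difference between the replicate sets were also chosen after their values were seen. With treatment as a block, 2313 of 19938 genes differed between set 2 and set 1 at an adjusted p under 0.05 in limma, 1204 higher and 1109 lower in set 2. The count was 1370 without either untreated array and 716 without either NaBu array. Genes of glycolysis and the response to low oxygen were higher in set 2 by a mean of 0.74, and 15 of 25 passed, including the carbonic anhydrase Car9 (2.33), Ndrg1 (2.11) and Vegfa (1.06). Targets of the unfolded protein and ATF4 responses were higher by 0.40, and 11 of 26 passed, including Atf3 (1.31), Chac1 (1.03) and Ddit3 (0.92). Both lists had adjusted p = 0.316 with an estimated correlation. Of 45 feeder fibroblast markers, 22 were higher and 2 lower, with the collagen crosslinker Lox at 2.38, Dcn at 2.29 and Col1a2 at 1.08, against Mgp at -2.17 (list adjusted p = 0.416 with an estimated correlation).

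Measured genes of the 2-cell-like list were lower in set 2 by a mean of -0.56, and 13 of 21 passed, including Pramel7 (-1.54) and Tmem92 (-1.38), but the list had adjusted p = 0.407 with an estimated correlation. As Zscan4a to Zscan4f, Dux and Tcstv1 were not measured, the list covers only part of this state. Germ cell genes went both ways, with 12 lower, including Asz1 (-2.33) and Tuba3b (-2.08), and 5 higher, including the synaptonemal gene Sycp3 (1.74). In the pluripotency list 7 genes were lower and none higher. The germline and pluripotency lists had adjusted p = 0.498 and 0.416 with an estimated correlation. Among the 43 genes called for VPA with the block, the median filter and robust eBayes with a trend were the repressor Rest (-0.63), the pluripotency factor Nr0b1 (-0.62), the imprinting factor Zfp57 (-0.73) and the immediate early gene Egr1 (0.87), all chosen after their values were seen.

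The lower pluripotency genes with VPA, with a mean of -0.36, could come from a single array, from more feeder RNA in the treated samples, or from the difference that separates the replicate sets. VPA replicate 1 alone cannot be told apart from an effect in both sets, since the mean of -0.27 in set 2 had a 95% interval from the spread between arrays of -0.58 to 0.04; without that array the list stayed called at a mean of -0.40 (interval between arrays -0.94 to 0.15, and -0.39 to -0.12 around -0.25 with the block), but this leaves 1 VPA array. Feeder RNA cannot be told apart either: the feeder markers were lower by -0.13 in set 1 and higher by 0.21 in set 2, and the sums of both means, -0.59 and -0.06, had intervals of -1.21 to 0.04 and -0.68 to 0.57. A difference between the sets that is equal in each group cancels here, since each group holds 1 array per set. An unequal one was examined only through the glycolysis and hypoxia list. Its mean of 0.02, in the ratio between the sets, would give -0.01 where the pluripotency mean was -0.36 (interval of the gap -0.56 to -0.15). This argues against an unequal difference only as far as that list follows it, and the list was chosen after the set differences were seen. An effect of VPA on the stem cells stays open beside the first 2 and beside an unequal difference that the list does not follow.

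Germ cell genes were higher with VPA by 0.41 in set 1 and by 0.01 in set 2. A low untreated array in set 1 might raise them, and it cannot be told apart from an effect of VPA, since VPA exceeded NaBu there by 0.18 with an interval of -0.29 to 0.66. A larger response of all genes in set 1 would give 0.24 in set 2, in the ratio of the pluripotency genes, and the observed mean was 0.0054. It cannot be told apart either, as the gap of -0.24 had an interval of -0.58 to 0.11. Whether the sets differ in their response was not tested, since each set holds 1 array per condition, and an effect of VPA stays open.

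The difference between the sets might reflect more feeder RNA in set 2. All genes made by the stem cells alone would then fall alike, but the 2-cell-like genes were lower by -0.56 and the pluripotency genes by -0.21, a gap of -0.35 (95% interval -0.57 to -0.14). As this list was picked for its low mean, the interval corrected for the choice among 23 lists was -0.95 to 0.24, and feeder RNA cannot be told apart from other sources for the lower genes. For the higher genes, feeder RNA alone would let none rise by more than the collagens Col1a1, Col1a2 and Col3a1, whose mean was 1.09. Of the genes called higher, 6.56% rose by more than that mean and the rest by less. That share holds the highest genes and no interval was taken for the gap, so the higher genes do not decide it either. Without the treatment term 1678 genes differed between the sets, the highest of the other splits into 3 and 3 called 0, and 1 split of 10 was as large, which are too few splits for a share under 0.05. No biological explanation was tested, since the design has no group for it.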
